A study of Homo sapiens with 8 samples.

How the data were processed

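Expression was measured on 8 single-colour Affymetrix arrays of total RNA from 2 brain-metastatic derivatives of human breast cancer lines, labelled 231BrM and SKBrM3. Per the labels, both lines carry a doxycycline-inducible short hairpin against MET, and each was grown with or without doxycycline (100 ng as the labels give it, with no volume) for 48 h. Each of the 4 groups holds 2 arrays. The deposited values are on the log2 scale, 1 per probe set and array, and were made by the authors with RMA (background correction, quantile normalization and summary per probe set), per the submitters' processing notes; its version, the software, the chip definition and the genome build are not given in the sources used here. The table holds 49386 probe sets, with values from 2.73 to 13.3 and array medians from 4.92 to 4.97. Quantile normalization gives every array nearly the same distribution, so a change of total RNA per cell cannot be seen. Scanner intensities and detection calls were not analysed here, so low values have no measured background. No genome build is named by the files, so no coordinates are given.

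Of the probe sets, 93 are control probe sets, 45259 name 1 gene, 1327 name several and 2707 are unnamed. Symbols of 45178 of those with 1 gene were updated by gene ID through a RefSeq gene table (assembly GRCh38.p14, used for names only), and 81 kept the symbol of the array annotation. For each of 18239 genes the probe set with the highest mean over the 8 arrays was taken. A gene was tested if its value exceeded 4.41 (the 40th percentile of all values) on at least 2 arrays, which left 13002 genes and set aside 5237. Other probe sets of each named gene were set beside the one used.

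Log2 values were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as 4 group means over all 8 arrays, with 4 residual and 4.59 prior degrees of freedom. The contrasts were the doxycycline effect in each line, their average, their difference, and the difference between the lines without doxycycline. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene is called higher or lower at an adjusted p under 0.05. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision: the median standard error of a doxycycline effect in 1 line was 0.0968 on the log2 scale.

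A total of 21 gene lists with 483 memberships, and the rule for named genes, were fixed before the data were examined. Of the memberships 400 were tested, which are 381 distinct genes, 18 of them in more than 1 list. Lists were tested with limma's camera at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes. The test with an estimated correlation is given beside it, and it differs in more than that correlation. For ATF4 stress response genes in 231BrM the estimate, 0.0061, lies below the preset. Yet the camera adjusted p rose from 0.00923 to 0.247. So a higher adjusted p with an estimated correlation is not by itself a sign of correlated genes. The fry test, which asks whether a list's genes move on balance in 1 direction, was run too, with the same adjustment. Counts of list members are given over all genes tested and adjusted over the list alone. CXCL8, CXCL1 and IL1B were named in advance because published work on MET in these lines is known to deal with them, so neither they nor the list of cytokines and chemokines is independent evidence of a direction.

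The rule for named genes is as follows. In both doxycycline comparisons it takes MET, CXCL8, CXCL1 and IL1B, the 7 highest and 7 lowest called genes whose doxycycline arrays both lie beyond both control arrays, and up to 3 members of each list with the smallest p among those with a p under 0.05 adjusted over the list alone. For the average it takes up to 7 called genes per direction with the same sign in both lines, for the difference up to 5 per direction, and for the lines without doxycycline the 5 highest, the 5 lowest and the members of both line marker lists, besides MET, CXCL8, CXCL1 and IL1B. TNFAIP3, PMVK and RGCC, which complete short counts, and the genes named from the array that stands apart or from outside the lists were chosen after their values were seen.

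The steps were tested on simulated data drawn for 13002 genes. Changes of 1.0 on the log2 scale were recovered for 99% of changed genes in each line. Changes of 0.5 were recovered for 68% in 231BrM and 79% in SKBrM3. There, 14 and 9 unchanged genes were called. A list shifted by -0.3 was called in both lines, with 0 of 20 other lists called at the same camera threshold. The noise was drawn independently for each gene, so list calls among correlated genes were not tested. Each gene had 1 spread for all groups. The wider spread of the 231BrM doxycycline arrays (SD of their difference over genes 0.255, against 0.124 to 0.138 in the other groups) was not simulated. Alternatives tried were other summaries of probe sets, no filter or a stricter one (60th percentile), repeated quantile normalization, subtraction of array medians, an intensity trend with robust moderation, array weights, fits of 4 arrays, a replicate block, a threshold of 0.10, an estimated correlation, other MET probe sets, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.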

Results

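The experiment asked how gene expression changes when the receptor tyrosine kinase MET is knocked down in brain-metastatic breast cancer cells. The 8 arrays form 4 groups of 2, the lines labelled 231BrM and SKBrM3 each with and without doxycycline, which switches on the hairpin. No group received doxycycline without a hairpin, so every doxycycline effect below holds the effects of the drug and of the hairpin together. Arrays of the same group correlated over genes at 0.992 to 0.998 and arrays of different lines at 0.957 to 0.964. The arrays of the 231BrM doxycycline group lay further apart than the others: 68 genes differed by over 2-fold between them, against 1, 1 and 0 in the other groups, and 66 of the 68 were lower on replicate 1. On that array the 3' minus 5' signal of the actin control probe sets was 1.24 log2 units, against 0.46 to 0.59 on the other 7 arrays. For GAPDH it was 0.33, against -0.02 to 0.09. The excess of 3' signal, a sign of shorter or degraded RNA, lies in the 231BrM doxycycline group alone, and counts without this array are given beside the doxycycline comparisons.

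**Figure D1:**
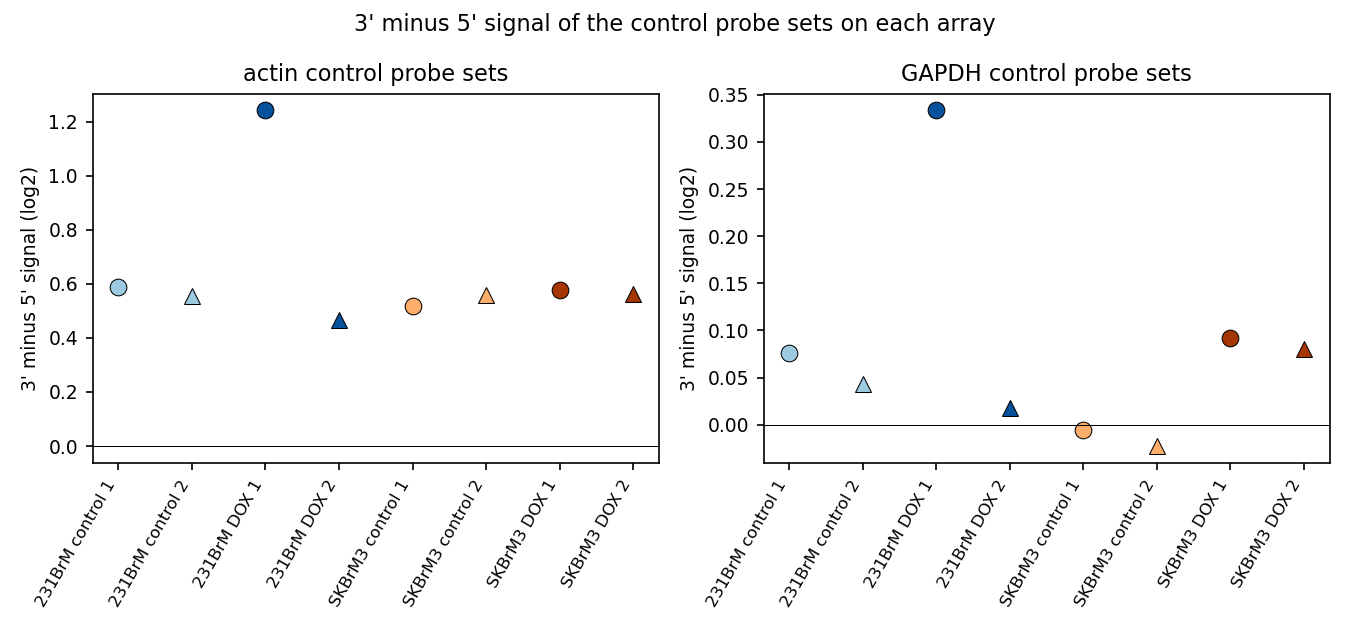
The 3' minus 5' signal (log2, y axis) of the actin (left) and GAPDH (right) control probe sets is plotted for each of the 8 arrays (x axis; circles replicate 1, triangles replicate 2). The first 231BrM doxycycline array lies at 1.24 and 0.33, above the highest of the other 7 arrays at 0.59 and 0.09.

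MET, the target of the hairpin, was 13.5-fold lower with doxycycline in 231BrM, falling from 9.35 ± 0.13 to 5.60 ± 0.35 (mean ± SD of log2 values, n = 2 per group). In the arrays labelled SKBrM3 it was 11.3-fold lower, falling from 9.23 ± 0.04 to 5.73 ± 0.03 (n = 2 per group). The log2 changes were -3.76 (standard error 0.148, limma adjusted p = 2.85e-05) and -3.50 (standard error 0.148, limma adjusted p = 1.32e-05). Of the 6 MET probe sets, the 4 that pass the filter gave log2 changes between -3.76 and -1.08 in 231BrM and between -3.50 and -1.67 in SKBrM3. Before doxycycline MET differed between the lines (231BrM minus SKBrM3) by 0.13 log2 units in the probe set used, with a 95% interval from -0.21 to 0.46. The other 3 probe sets that pass the filter gave -0.06, -0.63 and -0.14, and the mean of all MET probe sets gave -0.22 (limma adjusted p = 0.023), so the direction of this difference depends on the probe set.

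**Figure D2:**
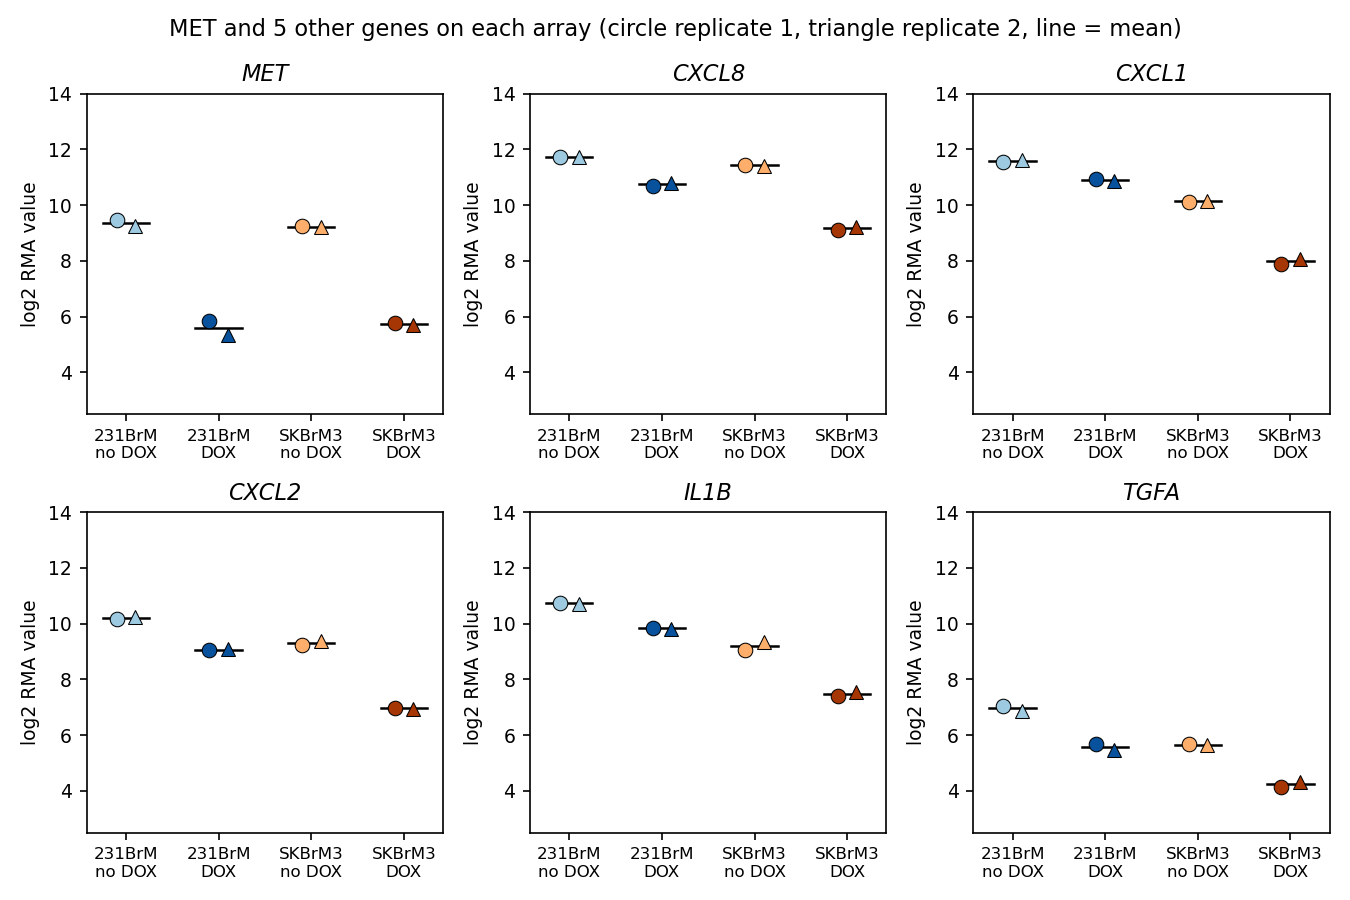
Log2 RMA values (y axis) of MET, CXCL8, CXCL1, CXCL2, IL1B and TGFA on each array, by line and doxycycline (x axis), with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 arrays. In each panel both doxycycline arrays lie below both arrays without doxycycline of the same line; MET ends at means of 5.60 and 5.73.

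In 231BrM, doxycycline lowered transcripts of inflammatory chemokines and of an EGF receptor ligand. CXCL2 fell by 1.12 log2 units (standard error 0.080), CXCL8, which encodes the neutrophil attractant interleukin-8, by 0.98 (0.081), IL1B, which encodes interleukin-1 beta, by 0.90 (0.108) and CXCL1 by 0.67 (0.084), each from 2 arrays per group. The other CXCL1 probe set that passes the filter gave -0.92. TGFA, an EGF receptor ligand, was 2.62-fold lower and SLITRK5, a neuronal transmembrane protein, 2.89-fold lower. DDIT4, an inhibitor of mTORC1 signalling, was 2.20-fold lower and BTF3L4 2.15-fold lower. EHHADH, an enzyme of peroxisomal fatty acid oxidation, was 2.19-fold lower, a fold limited by low signal, since its doxycycline mean of 4.17 lies under the filter level of 4.41. Over all genes, 21 were lower and 0 higher at a limma adjusted p under 0.05 (Benjamini-Hochberg), while 800 were higher and 486 lower at an unadjusted p under 0.05. Array weights called 11, all lower, and the 4 231BrM arrays alone called 1, MET. The other calls thus rest on the spread and degrees of freedom shared with the SKBrM3 arrays. The named falls had limma adjusted p-values from 0.00207 (CXCL2) to 0.0249 (CXCL1) besides that of MET. A fit without 1 of the 231BrM arrays leaves 1 array in its group and takes the spread from the other groups. Such counts show how the calls depend on single arrays and do not rest on replicates of that group. The fit without doxycycline replicate 1 called 80 genes, 78 lower and 2 higher, all 21 among them, and CXCL8 (-0.94), IL1B (-0.91) and TGFA (-1.50) were again lower there. The fit without replicate 2, which leaves that array alone in its group, called 1650, 1168 of them higher. Leaving out 231BrM control replicate 1 or 2 gave 3 and 4 genes, either SKBrM3 control array 13, and either SKBrM3 doxycycline array 11, all lower.

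By list, 4 of 21 cytokines and chemokines fell in 231BrM (CXCL2, CXCL8, IL1B and CXCL1) and 17 did not pass. Adjusted over the list alone, 8 were lower and 1 higher, which is not independent evidence since published work on these lines deals with this list's members. The mean log2 change of the list was -0.37 (camera adjusted p = 3.73e-13; adjusted p = 0.0344 with an estimated correlation). Without doxycycline replicate 1, the array with raised 3' signal, the mean was -0.44, with an adjusted p = 0.0929 with an estimated correlation. Of 18 NF-kB feedback and target genes, 0 passed over all genes by limma, while 8 were lower and 0 higher at an unadjusted p under 0.05, and the same number was lower adjusted over the list alone. Among these, ICAM1, an adhesion molecule, had a log2 change of -0.84 (limma adjusted p over all genes 0.0789), TNIP1 of -0.55 and NFKBIA, the NF-kB inhibitor, of -0.55. The camera test put this list below other genes (mean -0.28, adjusted p = 2.14e-11; adjusted p = 0.0874 with an estimated correlation). Without doxycycline replicate 1, which leaves 1 array in that group, the log2 changes were -0.96 for ICAM1, -0.35 for NFKBIA and -0.50 for TNIP1.

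Other lists with a downward camera call in 231BrM held few members that passed on their own. Hypoxia and glycolysis genes had a mean of -0.20 (camera adjusted p = 7.48e-09; adjusted p = 0.278 with an estimated correlation), with 0 of 24 called by limma, 6 lower at an unadjusted p under 0.05 and 4 lower adjusted over the list alone. NDRG1, a hypoxia-induced gene, had -1.08 and PFKFB3, a glycolytic regulator, -0.44, while other PFKFB3 probe sets gave 0.12, -0.16 and -0.08. In the angiogenic and EGF family growth factors (mean -0.17, camera adjusted p = 0.000125; adjusted p = 0.278 with an estimated correlation), TGFA fell and 17 of 18 did not pass, among them HBEGF at -0.51 and ANGPTL4 at -0.35. The list alone gave 3 lower after adjustment. ATF4 stress response genes (mean -0.08, camera adjusted p = 0.00923; adjusted p = 0.247 with an estimated correlation) held 1 called member of 25, DDIT4, which is also a target of other stress pathways, and 2 adjusted over the list alone. Cholesterol biosynthesis genes (mean -0.08, camera adjusted p = 0.00459; adjusted p = 0.426 with an estimated correlation) held 0 of 19 called by limma, 4 lower at an unadjusted p under 0.05 and 1 adjusted over the list alone, DHCR7 at -0.36. MET pathway components (mean -0.18, median -0.02, camera adjusted p = 0.0274; adjusted p = 0.507 with an estimated correlation) held MET alone as a called member of 22, over all genes and adjusted over the list alone. MET is the hairpin's own target, so the mean of this list includes the knockdown itself. ERK pathway output genes (mean -0.06, camera adjusted p = 0.0274; adjusted p = 0.471 with an estimated correlation) held 0 of 21 called by limma and 4 lower at an unadjusted p under 0.05, and ETV1, at -0.62, passed when adjusted over the list alone. Without doxycycline replicate 1 the camera adjusted p-values of MET pathway components and ATF4 genes were 0.0527 and 0.286. The means of cholesterol and ERK output genes were -0.15 and -0.12 there. ETV1 had a log2 change of -0.80 and HBEGF of -0.57 in that fit, which leaves 1 doxycycline array in 231BrM. The fry test, which asks whether a list's genes move on balance in 1 direction and not whether they differ from other genes, passed cytokines and chemokines (fry adjusted p = 0.00746) and proliferation (mean 0.08, fry adjusted p = 0.0156) in 231BrM. The other 7 lists with a camera call did not pass it, with fry adjusted p-values of 0.0657 for NF-kB, 0.138 for hypoxia and glycolysis, growth factors and ATF4, 0.26 for MET pathway components, 0.572 for cholesterol and 0.647 for ERK output.

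The remaining 13 lists gave no camera call in 231BrM. Their camera adjusted p-values ran from 0.0616 for proliferation (mean 0.08) and 0.0676 for the 231BrM markers (mean -0.04) to 0.982 for markers of fibroblasts, endothelium, leukocytes and astrocytes (mean 0.04). Between these lay mesenchymal genes (0.0738), endoplasmic reticulum chaperones (0.0772), genes linked to brain metastasis (0.0772), DNA replication (0.176), proteases (0.199), oxidative phosphorylation (0.394), SKBrM3 markers (0.471), interferon-stimulated genes (0.509), other receptor tyrosine kinases (0.632) and epithelial genes (0.742). Without doxycycline replicate 1, camera put proliferation higher (adjusted p = 0.000487; adjusted p = 0.163 with an estimated correlation) and the brain metastasis list lower (mean -0.15, adjusted p = 0.0277; adjusted p = 0.505 with an estimated correlation). No member of these 13 was called by limma over all genes. Those that passed adjusted over the list alone were MMP3 (log2 change 0.91), MMP9 (-0.53) and ADAMTS1 (-0.29) among the extracellular proteases, DNAJC3 (-0.63) among the endoplasmic reticulum chaperones, and ST6GALNAC5 (0.58), PTGS2 (-0.67), HBEGF and ANGPTL4 among the genes linked to brain metastasis. Without doxycycline replicate 1, from the 1 doxycycline array left, HBEGF, DNAJC3 and PTGS2 had log2 changes of -0.57, -0.83 and -0.86. Those of MMP9, ADAMTS1 and ANGPTL4 were -0.51, -0.36 and -0.32 there. The rises of MMP3 and ST6GALNAC5 were smaller in that fit, at 0.64 and 0.42. With all arrays, mean, median and camera direction differed in sign for 4 lists, none of them called: the proteases, epithelial genes, SKBrM3 markers and other cell types' markers.

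In the arrays labelled SKBrM3 the largest called falls after that of MET were those of 5 chemokines. CXCL2 was 5.07-fold lower, CXCL8 4.79-fold, CXCL1 4.42-fold, CXCL3 4.09-fold and CCL20 3.52-fold, with log2 changes from -2.34 (standard error 0.080) to -1.81 (0.151) and 2 arrays per group. For CXCL1 this holds for the probe set used, and the other that passes the filter gave a log2 change of -0.78. IL1B was 3.28-fold lower (log2 change -1.72, standard error 0.108) and BTF3L4 3.31-fold lower. Transcripts that rose included BIK, which encodes a pro-apoptotic BCL2 family protein, at 2.33-fold, HSD17B2, a steroid dehydrogenase, at 1.97-fold, IL18 at 1.81-fold and ST6GALNAC5, a sialyltransferase, at 1.73-fold. AOPEP, PRR16 and SLC43A1 rose by 1.80 to 1.83-fold. Other probe sets that pass the filter gave log2 changes of 1.22 and 0.14 for BIK, 0.62 and 0.11 for AOPEP and 0.52 and 0.12 for PRR16. For ST6GALNAC5 they gave 0.86, 0.63, 0.33 and 0.28, the last of them with 0.05 in 231BrM. The control level of PRR16, 4.36, lies under the filter level. These named genes had limma adjusted p-values from 6.22e-06 (CXCL2 and CXCL8) to 0.0225 (PRR16).

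Over all genes in the SKBrM3 arrays, 446 were called by limma, 296 lower (66.4%) and 150 higher. At an unadjusted p under 0.05 the balance was 1276 lower and 1355 higher. Of the 35 that changed by over 2-fold, 34 were lower, and BIK was the exception. The fits share 1 estimate of the spread, so the distance between the 231BrM doxycycline arrays enters here too. Without either of them 1631 genes were called, 833 higher and 798 lower (48.9%), with the 446 among them, and without replicate 1 36 of the 37 over 2-fold were lower. Array weights called 1604 (798 higher, 806 lower), and the 4 SKBrM3 arrays alone 1248 (627 higher, 621 lower). Leaving out either 231BrM control array gave 175 genes, SKBrM3 control replicate 1 or 2 gave 81 and 61, and SKBrM3 doxycycline replicate 1 or 2 gave 52 and 97.

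**Figure D3:**
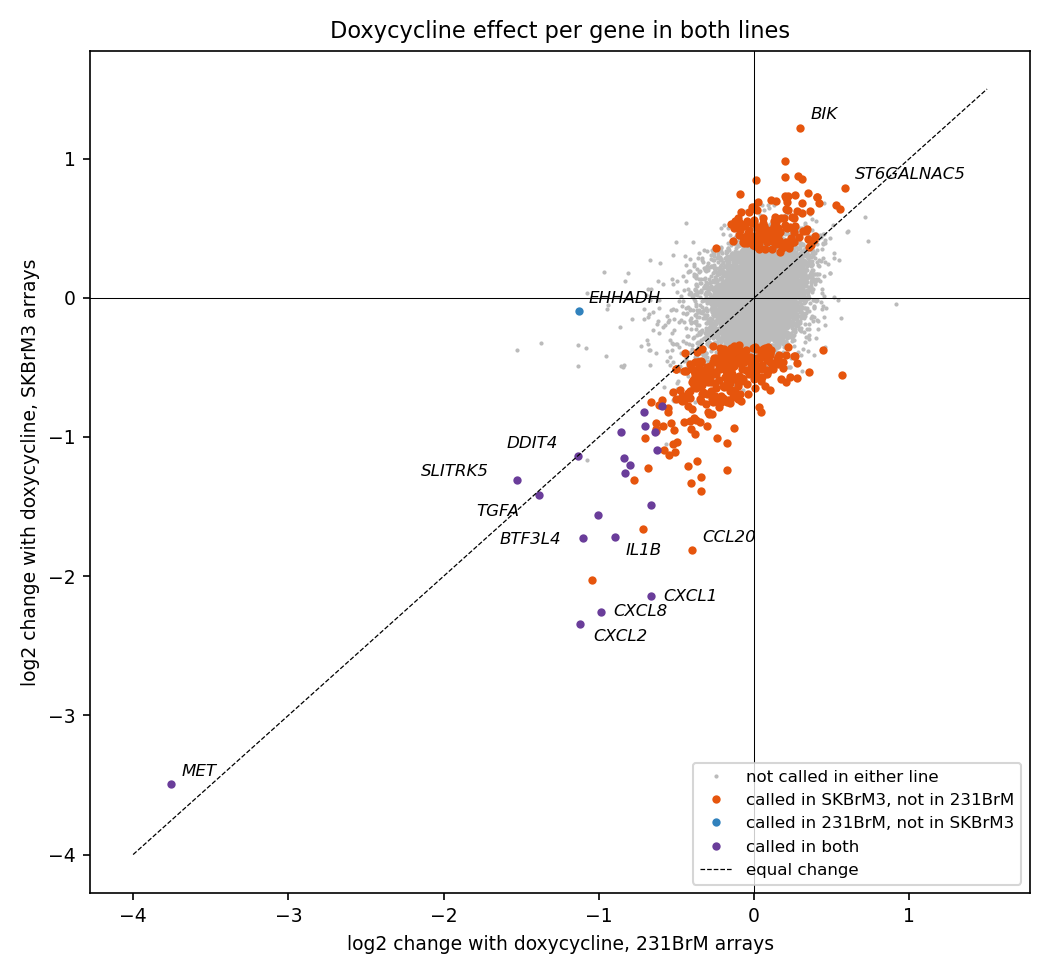
Each point is 1 of 13002 genes, with its log2 change with doxycycline in the 231BrM arrays (x axis) and in the arrays labelled SKBrM3 (y axis); colours mark genes called by limma at an adjusted p under 0.05. MET lies at -3.76 and -3.50, and CXCL1, CXCL2 and CXCL8 lie below the dashed line of equal change.

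Of 21 cytokines and chemokines, 8 fell and 1, IL18, rose in the SKBrM3 arrays (0.85), and 12 did not pass. With adjustment over the list alone 9 were lower and 1 higher, again not independent evidence. The list's mean was -0.72 and its median -0.22 (camera adjusted p = 2.82e-10; adjusted p = 0.0551 with an estimated correlation). Of 18 NF-kB feedback and target genes, 4 fell: BCL2A1, an anti-apoptotic target gene, by 1.29 log2 units, NFKBIA by 0.82, NFKBIZ by 0.67 and TNFAIP3, which restrains NF-kB signalling, by 0.61. Of these 18, 11 were lower adjusted over the list alone (mean -0.41, camera adjusted p = 1.54e-08; adjusted p = 0.148 with an estimated correlation). Of 19 cholesterol biosynthesis genes, 8 fell and 1, PMVK, rose (0.46), and adjusted over the list alone 11 were lower and 1 higher. INSIG1, a sterol-regulated brake on the pathway, fell by 0.88, and the enzymes MSMO1 and IDI1 fell by 0.73 and 0.62 (list mean -0.35, camera adjusted p = 1.54e-08; adjusted p = 0.22 with an estimated correlation).

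Hypoxia and glycolysis genes had a mean of -0.27 in the SKBrM3 arrays (camera adjusted p = 2.99e-06; adjusted p = 0.323 with an estimated correlation). HK2, a hexokinase, fell by 0.73 and PFKFB3 by 0.53, and 22 of 24 did not pass, NDRG1 among them at -1.16 (called by limma without the apart-lying 231BrM array), while 7 were lower adjusted over the list alone. Among 25 ATF4 stress response genes, DDIT4 fell by 1.14, MTHFD2, a mitochondrial folate enzyme, by 0.53 and XPOT, a tRNA export factor, by 0.40, and 22 did not pass (mean -0.14, camera adjusted p = 0.0151; adjusted p = 0.22 with an estimated correlation). The list alone gave 6 lower and 1 higher after adjustment. Among 18 angiogenic and EGF family growth factors, TGFA fell by 1.42, HBEGF by 0.73 and EREG by 0.66, all 3 of them EGF receptor ligands, and the same number passed adjusted over the list alone (mean -0.18, camera adjusted p = 0.0209; adjusted p = 0.625 with an estimated correlation). The change of TGFA is limited by low signal, since its doxycycline mean of 4.24 lies under the filter level of 4.41. Without the apart-lying 231BrM array the camera adjusted p of this last list was 0.0537. The fry test passed cytokines and chemokines (fry adjusted p = 0.000722), NF-kB, cholesterol, ATF4 and proliferation genes (each with a fry adjusted p of 0.0118) and hypoxia and glycolysis genes (fry adjusted p = 0.0483) in the SKBrM3 arrays, and growth factors missed it (fry adjusted p = 0.0706).

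The other 15 lists gave no camera call in the SKBrM3 arrays, with adjusted p-values from 0.0884 (epithelial genes, mean -0.12) to 0.823 (MET pathway components, whose mean of -0.11, median of 0.03 and upward direction differ in sign). Members of them that rose were the kinase SRC (0.36), the VEGF receptor KDR (0.39, from a control level of 4.33, under the filter level), the plasminogen activator PLAT (0.42), and RGCC (0.57) and ST6GALNAC5 (0.79) from the brain metastasis list. Members that fell besides MET were EGR1 (-0.78) and IER3 (-0.55), 2 immediate early genes, the proteases ADAMTS1 (-0.82) and MMP9 (-0.68), the replication factor MCM10 (-0.55), the chaperone DNAJC3 (-0.90), and HBEGF (-0.73) and CSF3 (-0.74) from the brain metastasis list. Other probe sets that pass the filter gave -0.82, -0.64, -0.13 and -0.09 for EGR1, -0.19 and -0.31 for MCM10 and -1.14 and -0.25 for DNAJC3. With the probe sets used each had a limma adjusted p under 0.05, the weakest being that of SRC at 0.0478. FOSL1, an ERK pathway output gene, rose by 0.66. It passed adjusted over the list alone but not over all genes (limma adjusted p = 0.0557). The counts lower and higher adjusted over the list alone were 4 and 1 for ERK pathway output, 2 and 2 for MET pathway components, 4 and 2 for proteases, 2 and 1 for mesenchymal genes, 2 and 2 for the brain metastasis list, 3 and 0 for the 231BrM markers, 1 and 1 for endoplasmic reticulum chaperones, and 1 in all for DNA replication (MCM10), for other receptor tyrosine kinases (KDR) and for other cell types' markers (PECAM1, -0.35, called over all genes without the apart-lying 231BrM array).

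**Figure D4:**
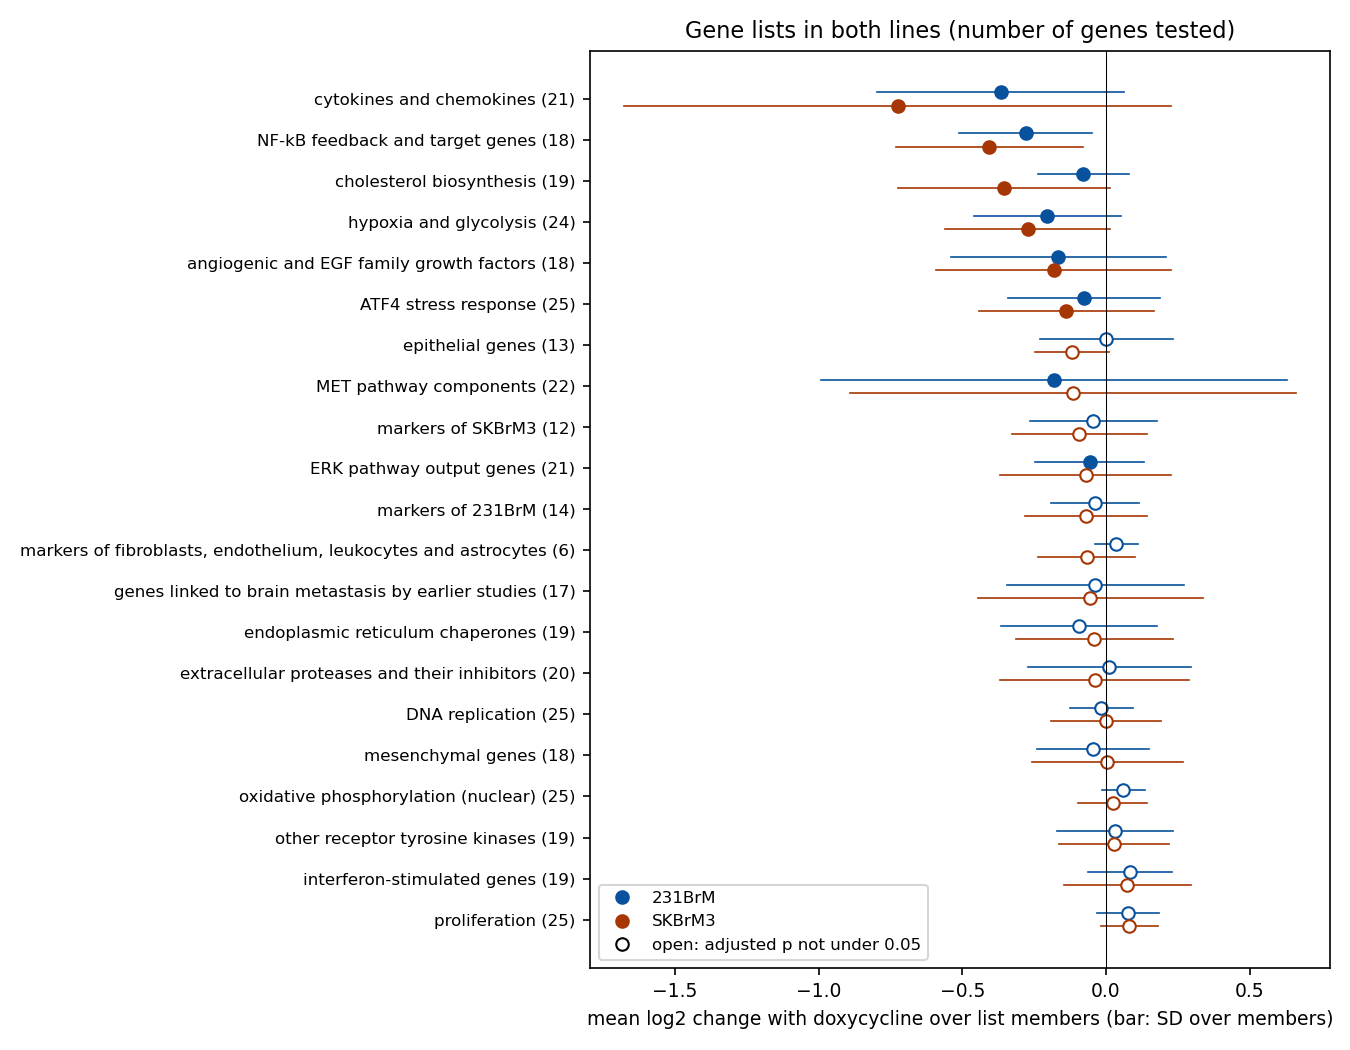
Mean log2 change with doxycycline (x axis) of the 21 gene lists (y axis, with the number of genes tested), in 231BrM and in the arrays labelled SKBrM3; bars show the SD over list members and filled points a camera adjusted p under 0.05 at the preset correlation. Cytokines and chemokines have means of -0.37 and -0.72.

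Averaged over both lines, the fall of MET (log2 change -3.63, standard error 0.105) was accompanied by falls of CXCL2 (-1.73, 0.056), SLITRK5 (-1.42, 0.096), BTF3L4 (-1.41, 0.067), TGFA (-1.40, 0.077), DDIT4 (-1.14, 0.099) and NDRG1 (-1.12, 0.190), with 4 arrays against 4. These genes rank first by the smaller change of the 2 lines, not by the average. CXCL8 (-0.98 in 231BrM and -2.26 in SKBrM3) and IL1B (-0.90 and -1.72) fell in both lines too and rank lower by this rule. The value of TGFA holds the low signal of its SKBrM3 doxycycline arrays. Rises were smaller: ST6GALNAC5 rose by 0.69 (0.083), CCND2, which encodes cyclin D2, by 0.65 (0.124), OSGEPL1 by 0.60 (0.079), AHNAK2 by 0.59 (0.098), the interferon-inducible GTPase GBP3 by 0.54 (0.113), the transcription factor FOXQ1 by 0.52 (0.083) and CT83 by 0.46 (0.093). Without the apart-lying 231BrM array these rises were, in the same order, 0.61, 0.51, 0.56, 0.49, 0.42, 0.53 and 0.34. All but that of FOXQ1 were smaller there. With all arrays 395 genes were called by limma, 269 lower (68.1%) and 126 higher, while at an unadjusted p under 0.05 the balance was 946 lower and 1516 higher. The balance of the called genes depends on single arrays: without 231BrM doxycycline replicate 2 more of them rose than fell. Without the apart-lying array 686 were called, 495 lower and 191 higher, with the 395 among them. Without 231BrM doxycycline replicate 2 the count was 2887, without 231BrM control replicate 1 or 2 it was 107 and 98, without SKBrM3 control replicate 1 or 2 it was 124 and 109, and without SKBrM3 doxycycline replicate 1 or 2 it was 119 and 150. By camera 7 lists were lower and 1, proliferation, higher (mean 0.08, adjusted p = 0.0162; adjusted p = 0.155 with an estimated correlation), with 0 of 25 proliferation genes called by limma over all genes or adjusted over the list alone and 5 higher at an unadjusted p under 0.05. Cytokines and chemokines had a mean of -0.55 (camera adjusted p = 9.29e-15; adjusted p = 0.0276 with an estimated correlation), the 1 list called in both ways, with 9 members lower and 1 higher over all genes and 13 lower and 1 higher adjusted over the list alone. Without the apart-lying array its adjusted p = 0.0655 with an estimated correlation. There camera also put epithelial genes and the brain metastasis list lower (each with an adjusted p of 0.0464; adjusted p = 0.329 and 0.396 with an estimated correlation). The other 6 lower lists, those of NF-kB, hypoxia and glycolysis, cholesterol, growth factors, ATF4 and ERK output, had adjusted p-values of 0.0674, 0.155, 0.155, 0.28, 0.14 and 0.547 with an estimated correlation. The fry test passed 7 of these 8 lists, with fry adjusted p-values from 0.000331 (cytokines and chemokines) to 0.0243 (growth factors), and ERK output missed it (fry adjusted p = 0.242). Mean, median and direction differed in sign for 4 lists, none of them called.

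Of the 21 genes that fell in 231BrM, MET among them, 20 also fell in the SKBrM3 arrays, against 0.478 expected from independent lists (two-sided Fisher's exact test over 13002 genes, p = 1.51e-32), and EHHADH did not pass there (-0.10). Its SKBrM3 control level of 3.80 lies under the filter level of 4.41, so low signal may hide a fall of EHHADH in SKBrM3. Whether it does was not tested, since low values have no measured background here. The comparisons share no arrays but share the estimate of the spread. With 1 array left out the shared calls numbered 64 and 337 without 231BrM doxycycline replicate 1 or 2 (204 of the 337 higher), 3 without either 231BrM control array, 12 without either SKBrM3 control array and 10 without either SKBrM3 doxycycline array. Of the 296 genes lower in the SKBrM3 arrays, 238 (80.4%) had a negative change in 231BrM, with a median of -0.21 against -0.57. Of the 150 that were higher, 111 (74.0%) had a positive change in 231BrM, with a median of 0.10 against 0.48. For comparison, 57.1% of all genes had the same sign. The median change of all genes in 231BrM was 0.05, so positive signs were the more common there. The share of 57.1% is therefore no direct background for rises or for falls taken alone. Log2 changes of both lines correlated across genes with Pearson's r = 0.388 and Spearman's rho = 0.237, a description only, since genes are not independent replicates.

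The chemokines CXCL8 and CXCL2 fell less in 231BrM than in the arrays labelled SKBrM3, as did CXCL1 by 1 of its probe sets. The differences of the log2 changes (231BrM minus SKBrM3) were 1.27 (standard error 0.114) for CXCL8, 1.22 (0.113) for CXCL2 and 1.48 (0.119) for CXCL1, each with a limma adjusted p of 0.0114 for the interaction from 2 arrays in each of 4 groups. The other CXCL1 probe set that passes the filter fell by 0.92 in 231BrM and by 0.78 in SKBrM3, the opposite order. The other CXCL8 and CXCL2 probe sets keep the order, 1 for CXCL8 with -1.08 in 231BrM and -2.98 in SKBrM3. With the mean of a gene's probe sets 2 genes passed, CXCL8 and CXCL2, and CXCL1 did not. No other gene passed with the probe sets used, and 1452 had an unadjusted p under 0.05. Without the apart-lying array 5 genes passed, with NIPSNAP1 and EHHADH (-1.03 and -1.13; chosen after their values were seen) added to these 3. For EHHADH the low SKBrM3 level may hide a fall. The count was 473 without 231BrM doxycycline replicate 2, 1 without SKBrM3 doxycycline replicate 2, and 0 by limma without any 1 of the other 5 arrays. Camera put 2 lists higher in the difference: cytokines and chemokines (mean 0.36, adjusted p = 0.00305; adjusted p = 0.49 with an estimated correlation) with 3 of 21 called and 8 higher and 3 lower adjusted over the list alone, and cholesterol biosynthesis (mean 0.28, adjusted p = 0.000647; adjusted p = 0.992 with an estimated correlation) with 0 of 19 called by limma, 9 higher and 1 lower at an unadjusted p under 0.05 and 6 higher adjusted over the list alone. By fry the first passed (adjusted p = 0.0263) and the second did not (fry adjusted p = 0.251). Mean, median and direction differed in sign for 8 other lists, none of them called.

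Without doxycycline the lines differed widely: ADGRF5, an adhesion G protein-coupled receptor, was 59.0-fold, PAGE5 51.2-fold, the gap junction gene GJA1 50.3-fold, the transglutaminase gene TGM2 46.0-fold and SHISA2 43.1-fold higher in 231BrM. LCP1, an actin-bundling protein, was 31.3-fold, the proteoglycan gene VCAN 23.6-fold, PTPRN2 18.5-fold, the neuropeptide gene GAL 14.2-fold and FGF13 10.1-fold higher in the arrays labelled SKBrM3. The limma adjusted p-values of these 10 genes lay between 3.91e-09 and 4.54e-07, with 2 arrays per line. In the line with the lower level, ADGRF5, PAGE5, GJA1, TGM2, VCAN and PTPRN2 lie under the filter level of 4.41, so their folds are limited by low signal and set no order. Folds are those of the probe set with the highest mean: the other GJA1 probe set that passes the filter gave a log2 difference of 0.60, and those of TGM2 gave 0.72, 2.17 and 1.02. CXCL1 and IL1B were higher in 231BrM by 1.44 (standard error 0.084) and 1.54 (0.108) log2 units, and CXCL8 by 0.31 (0.081), while the other CXCL8 probe sets that pass the filter gave 0.09 and 0.10. Over all genes 5167 were called, 2580 higher and 2587 lower in 231BrM, and 703 of them differed by over 2-fold. Without 231BrM control replicate 1 the count was 3324 and without SKBrM3 control replicate 2 it was 3432.

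In the arrays labelled SKBrM3, markers of that line did not follow what its name implies. SKBrM3 is known as a derivative of SK-BR-3, a luminal line with amplified ERBB2, and 231BrM as a derivative of the mesenchymal line MDA-MB-231. ERBB2 was 6.71 ± 0.02 in the control arrays labelled SKBrM3 and 6.81 ± 0.08 in those of 231BrM (SD, n = 2), a difference of 0.10 with a 95% interval from -0.11 to 0.32. Its neighbours GRB7 and STARD3 differed by -0.06 and -0.07 (231BrM minus SKBrM3, limma adjusted p = 0.778 and 0.572), and PGAP3 and MIEN1 were lower in 231BrM, with differences of -0.31 and -0.73. The luminal keratins KRT19, KRT7, KRT8 and KRT18 were higher in 231BrM, by 2.59, 1.90, 1.07 and 0.63, as was SPDEF, by 0.83, while FOXA1 was lower there (-1.37) and AZGP1 differed by -0.01. The mesenchymal marker VIM was at 12.89 in 231BrM and 12.75 in the arrays labelled SKBrM3, AXL at 11.52 and 11.33 and CD44 at 11.58 and 11.41 (limma adjusted p = 0.189, 0.151 and 0.0877). Of the other 231BrM markers, SPARC, PLAU, LOX, PLAUR, CAV2 and CAV1 were higher in 231BrM by 2.73, 0.95, 0.89, 0.73, 0.63 and 0.55 (SPARC lies under the filter level in the SKBrM3 arrays), GSTP1 was lower (-1.21), and ANXA1, MSN, CD274 and TGFBI differed by 0.13, -0.03, -0.07 and -0.24 without passing.

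Camera called 12 lists between the lines without doxycycline, 9 higher and 3 lower in 231BrM, and 0 with an estimated correlation, where adjusted p-values ran from 0.261 to 0.627 over all 21 lists. The fry test passed 18 lists, these 12 among them, with fry adjusted p-values up to 0.0456. Extracellular proteases and their inhibitors were higher (14 of 20 members higher and 2 lower, mean 0.75, camera adjusted p = 1.92e-05; adjusted p = 0.364 with an estimated correlation), as were interferon-stimulated genes (11 of 19 higher, mean 0.71, camera adjusted p = 0.000125; adjusted p = 0.364 with an estimated correlation) and mesenchymal genes (9 of 18 higher and 1 lower, mean 0.76, camera adjusted p = 0.00196; adjusted p = 0.261 with an estimated correlation). Lists lower in 231BrM were cholesterol biosynthesis (11 of 19 lower and 1 higher, mean -0.42, camera adjusted p = 0.00818; adjusted p = 0.364 with an estimated correlation), DNA replication (10 of 25 lower and 2 higher, mean -0.26, camera adjusted p = 0.0283; adjusted p = 0.364 with an estimated correlation) and nuclear oxidative phosphorylation genes (12 of 25 lower and 1 higher, mean -0.22, camera adjusted p = 0.0301; adjusted p = 0.501 with an estimated correlation). With adjustment over the list alone these counts were 14 and 2 for proteases, 11 higher and 1 lower for interferon-stimulated genes, 9 and 1 for mesenchymal genes, 12 lower and 2 higher for cholesterol, 14 lower and 3 higher for replication, and 12 lower and 1 higher for oxidative phosphorylation. The other lists called higher in 231BrM were cytokines and chemokines (11 of 21 higher and 2 lower, mean 0.62, camera adjusted p = 0.00196), MET pathway components (9 of 22 higher and 1 lower, 0.37, 0.00196), 231BrM markers (6 of 14 higher and 1 lower, 0.40, 0.0112), epithelial genes (8 of 13 higher and 1 lower, 0.62, 0.0184), endoplasmic reticulum chaperones (8 of 19 higher and 3 lower, 0.23, 0.0301) and genes linked to brain metastasis (8 of 17 higher and 3 lower, 0.46, 0.0311). The SKBrM3 markers, with 5 of 12 higher and 3 lower in 231BrM, were not called (mean 0.38, median 0.04, camera adjusted p = 0.155). The ERK output list, not called, had a mean of 0.18 and a median of -0.01.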

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

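The tests of the ERBB2 region and of genes abundant in 231BrM, and that of distance from the controls, were chosen only after the result was seen, as was the ratio taken after array medians; the other tests below were set beforehand. CXCL8 and CXCL2 changed differently in the 2 lines by the interaction test, with differences of 1.27 and 1.22 log2 units (231BrM minus SKBrM3). CXCL1 did so by the probe set used, with 1.48, but not by its other probe set, which changed by -0.92 in 231BrM and -0.78 in SKBrM3. As lists, cytokines and chemokines and cholesterol biosynthesis differed between lines by means of 0.36 and 0.28, which did not pass with an estimated correlation (adjusted p = 0.49 and 0.992). Among 2296 probe sets that name no gene or several, left out of all comparisons, limma called 40 in the SKBrM3 arrays (8 higher, 32 lower).

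The arrays labelled SKBrM3 lacked the ERBB2-amplified luminal profile their name implies. An exchange of labels between the lines would place ERBB2 at least 2 log2 units higher in the arrays labelled 231BrM, and the difference was 0.10, which argues against it. Failure of the ERBB2 probe sets alone is argued against by the amplicon neighbours GRB7, STARD3, PGAP3 and MIEN1, which lay a median of 0.19 higher in the SKBrM3 arrays where at least 2 was predicted. SKBrM3 cells hidden by 231BrM cells would need these as most of the RNA, yet 19 of 2318 genes abundant in 231BrM lay over 2 log2 units lower in the SKBrM3 arrays (a share under 25%), 15 of them at SKBrM3 levels above the filter, such as SHISA2 and IGFBP3 at 2.32 and 4.58% of their 231BrM level, which argues against it. A line of other origin under this name, a mixture with other mesenchymal cells, or loss of the profile in the derivative may apply and was not tested.

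The first 231BrM doxycycline array lay apart from the second. Degraded RNA may be the source: its 3' minus 5' signal exceeded the highest of the other 7 arrays for actin and for GAPDH, the smaller excess being 0.24 log2 units, in a test set before these probe sets were read. A weaker response of that culture as the source is argued against, since it would place the array nearer the controls, and of the 68 genes over 2-fold apart 0 lay nearer the 231BrM controls on it (median change -1.14, against 0.12 on the second). Whether its response was also weaker stays open: over the 296 genes lower in SKBrM3 the ratio of median changes, replicate 1 over replicate 2, was 0.636, which met the bound of 0.67 set for it, but 0.992 after each array's median change over all genes (0.10 and -0.00133) was taken off, so the response and the array's overall shift cannot be told apart by this ratio. Another state of that culture was not tested.

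Among genes called by limma more fell than rose with doxycycline, whereas at an unadjusted p under 0.05 more rose (1516 against 946 in the average, 1355 against 1276 in SKBrM3, 800 against 486 in 231BrM). The median change over all genes was positive too (0.03, 0.01 and 0.05 in that order), and counts of small changes follow such an offset. So the unadjusted counts do not show by themselves that more transcripts rose. Among called genes of the average, too, the balance turned to rises without 231BrM doxycycline replicate 2. A misleading choice of probe set is argued against by 478 other probe sets of the genes lower in the average, whose median change was -0.36, with 94.1% negative. An action of the hairpin on transcripts other than MET cannot be told apart from an effect of MET loss, since neither hairpin nor 3' UTR sequences were used here; 13 genes outside every list fell in both lines. The doxycycline effect averaged over both lines, with 395 genes, exceeded the other splits of the 8 arrays into 4 and 4. Of 34 splits 1, the real one, gave as many, a share under 0.05, and the highest other gave 57. But the 18 splits that divide both lines equally (highest other 3) are too few for such a share. Most other splits also join arrays with and without doxycycline, so the doxycycline effect widens their spread and tends to lower their counts. The share therefore does not decide by itself whether the calls exceed chance. The excess of falls over rises in SKBrM3 was absent among all 1631 calls without either 231BrM doxycycline array, so part of it may come from the spread between these arrays, which does not single out replicate 1.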

How the results depend on the processing

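No alternative below was added after the data were examined. Every count is of genes called by limma unless a list is named. MET fell in both lines under every change of filter, scaling, moderation, weighting, block or left-out array; its 2 probe sets whose levels lie under the filter (-0.0712 and -0.20 in 231BrM, -0.38 and -0.43 in SKBrM3) did not pass. Testing all probe sets gave 0 for the difference of effects and 10353 for the lines without doxycycline. More features are tested there (at most 49386 probe sets, against 13002 genes), but their number is not the only change. At the same log2 change, the limma adjusted p of MET in 231BrM went from 2.85e-05 to 0.00133, a larger rise than that in features. An intensity trend with robust moderation gave 45 genes in 231BrM, 13 for the difference and 39 shared by both lines. Array weights gave 11 in 231BrM, 1604 in SKBrM3 and 10 shared. Fits of only 4 arrays gave 1 (MET) and 1248. An adjusted p under 0.10 gave 33, 909, 761 for the average and 7 for the difference. Without a filter 1 list was called for the difference, and with an estimated correlation 1, 0, 1, 0 and 0 lists in 231BrM, SKBrM3, the average, the difference and the lines without doxycycline. With the mean of a gene's probe sets, MET between the lines without doxycycline turned to -0.22 (adjusted p = 0.023). Leaving out each array in turn, with a lone array assumed to vary like the others, gave 3 to 1650 genes in 231BrM, 52 to 1631 in SKBrM3, 98 to 2887 in the average, 0 to 473 for the difference, 3324 to 6576 without doxycycline and 3 to 337 shared; for lists, 5 to 8 in 231BrM and 1 to 3 for the difference. In 231BrM the counts were 3 and 4 without the first and second 231BrM control, 80 and 1650 without the first and second 231BrM doxycycline array, 13 without either SKBrM3 control and 11 without either SKBrM3 doxycycline array. In SKBrM3 they were 175 and 175, 1631 and 1631, 81 and 61, and 52 and 97 in that order; in the average 107 and 98, 686 and 2887, 124 and 109, and 119 and 150. Dropping either array of the 231BrM doxycycline group removes their spread from the shared estimate. Each left-out array also takes 1 of the 4 residual degrees of freedom. Leaving out an SKBrM3 array keeps every log2 change in 231BrM as it was (MET at -3.76). The lower 231BrM counts there thus come from the estimate of the spread and its degrees of freedom. How far the other shifts rest on this was not tested. Replicate numbers pair only 2 arrays per line and group and their deviations correlated at 0.239 and -0.0123, so they were not taken as pairs; a replicate block gave 20, 482, 442, 4 and 5112 genes, 17 shared, and changed no count by over 1.5 times. In the next counts a change of sign stands apart only where the value passed the threshold in the main fit or the alternative. Otherwise it counts as the same side. For 99 results on single named genes, the alternatives other than left-out arrays gave 879 values on the same side of the threshold, 46 that lost it, 38 that gained it and 1 such change of sign (that of MET above). Leaving out each array gave 581, 179 and 32, the most losses, 35, without the first SKBrM3 doxycycline array. Low signal limits 5237 genes that were not tested.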

Other observations

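Several of the genes that fell in both lines belong to no list fixed in advance and were chosen after their values were seen. PURA, which encodes a single-stranded nucleic acid binding protein, fell by 1.01 log2 units in 231BrM (standard error 0.098) and by 1.56 in the arrays labelled SKBrM3. In the same order, SGMS2, a sphingomyelin synthase, had log2 changes of -0.66 and -1.49, B3GNT5, a glycosyltransferase of the lacto-series glycolipids, of -0.83 and -1.26, the microtubule-binding gene EML4 of -0.86 and -0.96, and C21orf91 of -0.84 and -1.15. All had a limma adjusted p under 0.05 in each line, the weakest being those of EML4 and SGMS2 in 231BrM at 0.0249, with 2 arrays per group.

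The genes lowest on the first 231BrM doxycycline array against the second were GOLIM4 (a difference of -3.13), the histone gene H2AC20 (6.64 against 9.57), the BMP antagonist gene NOG (7.01 against 9.66), the chaperone gene CALR (5.77 against 8.26), MIX23 (3.67 against 5.97), ANKRD1 (6.47 against 8.71), CBX5 (6.51 against 8.56) and the long noncoding RNA MALAT1 (9.09 against 11.11). GOLIM4 and MIX23 lie under the filter level of 4.41 on the first array, so their differences are limited by low signal. The means of the 231BrM control arrays for CALR, ANKRD1 and MALAT1 were 7.97, 8.73 and 10.95.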
